A study of Homo sapiens with 2 samples.

How the data were processed

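Total RNA of parental and ECF-resistant MKN-28/74 gastric cancer cells was sequenced after library preparation with a SMARTer messenger RNA kit, per the labels' protocols. There were 2 libraries, 1 per group, and each deposited table gave 1 value per gene symbol for 1 library. Per the submitters' processing notes, TopHat and Cufflinks were used with the genome build hg19. Their versions, parameters and annotation are not given in the sources used here. The deposited values were taken as FPKM, fragments per kilobase of transcript, scaled to the number of mapped fragments, because the labels name Cufflinks and the values are not whole and sum to different totals, but no header names the unit. FPKM scaling already divides by library size and gene length, and it leaves a library's composition in the values, so that a few very abundant genes lower all others. The 10 most abundant genes on chromosomes 1 and 10 to 18 took 17.4% of the sum there in the parental and 17.5% in the resistant library. The smallest value above 0 was 0.002 in both tables. No counts were given, so depth is unknown and no counting interval was computed.

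From the deposited values, the log2 ratio of resistant over parental was computed per gene with a pseudocount of 1 FPKM, which understates the difference of low genes. Genes entered a count or list if they reached 1 FPKM in at least 1 library, and a 2-fold ratio on that scale was the threshold. With 1 library per group there is no test across genes, no standard deviation and no replicate check. Gene lists, named genes and most alternatives were fixed before the data were examined. For each of 45 gene lists, the median log2 ratio was placed among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean expression. That percentile describes these 2 libraries only, and it was given for lists with at least 5 measured genes. A measured gene of a list is one at 1 FPKM or more in at least 1 library. The tables held 1193 of the 1217 list entries. Gene symbols were unique. Genes to be named were 4 genes of the study's topic, the 15 highest and 15 lowest log2 ratios among genes at 5 FPKM or more in at least 1 library without small RNAs, the 2 to 4 measured members of each list with the largest ratio in either direction (with the 2 most abundant where none passed 2-fold), and the 5 most abundant genes of each library. Other genes named were chosen after their values were seen, and this holds for the neighbours of ERBB2 and for single list members that were added to describe a group. A few genes that the rule selects are not reported here.

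Symbols were matched to chromosomes through a reference gene table of another build, GRCh38, used for chromosome and neighbour order only, and 23277 of 24391 matched 1 chromosome. Because both tables hold values only for some chromosomes, each result was recomputed on chromosomes 1 and 10 to 18, a choice made after seeing the data, and the named genes were also taken by the same rule among those chromosomes. Medians over 15 and over 25 neighbouring genes were set against 1000 random gene orders, also chosen after seeing the data. The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to a common sum, by the median ratio or by the upper quartile (percentile 75), fold thresholds of 1.5 and 4, the first entry per symbol, and random lists not matched on expression.

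The computation was tested on simulated data made from the values of 6066 genes, with the same normal noise for every gene. The size of that noise was set by hand, because no replicate gives one. Among genes at 5 FPKM or more in at least 1 simulated library, all 94 changed by a log2 ratio of 2 and all 93 changed by 3 were recovered past 2-fold. Of all unchanged genes, 0.0514% were called. These shares check the computation at that noise, and they are not error rates for the 2 real libraries. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.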

Results

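The study measured messenger RNA by bulk RNA sequencing in a gastric cancer cell line, named MKN-28/74 in the labels, and in a derivative selected for resistance to ECF, the usual abbreviation of the drug combination epirubicin, cisplatin and fluorouracil. The resistant cells came from repeated exposure to increasing ECF concentrations with drug-free recovery in between, and were then kept under periodic treatment. The title of the series puts the question: whether NINJ2, which encodes the membrane adhesion protein ninjurin 2, and cancer-initiating cells are linked to chemoresistance. There was 1 library of parental cells and 1 library of ECF-resistant cells, so no value has a replicate error, no test between the groups was possible, and each difference is one between 2 libraries. Values are FPKM, a unit inferred from the named quantification tool. Sequencing depth is unknown, because no counts were given.

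Both deposited tables listed 24391 genes. The parental table held 8170 genes above 0 and the resistant one 8675, and 5641 and 6287 genes reached 1 FPKM. The values summed to 471329 FPKM in the parental and 618161 FPKM in the resistant library. Values above 0 were almost limited to chromosomes 1 and 10 to 18, which held 10492 of the genes matched to a chromosome. The share of genes above 0 lay between 59.0% and 84.0% per chromosome in the parental library and between 55.1% and 83.7% in the resistant one. On chromosome 19 the parental library had 3 of 1542 genes above 0, while the resistant library had values up to CEACAM6, for 741 of 915 genes. Among the 11243 genes of the other 13 chromosomes, 4 and 2 were above 0, and genes that every cell uses, such as those of 33 ribosomal proteins, were listed at 0 there. A gene listed at 0 on those chromosomes therefore says nothing about its expression. The comparison was designed on all genes. The account here leads with chromosomes 1 and 10 to 18, a restriction chosen after seeing the data, and adds the counts and correlations over all genes, and a list's result over all genes where its call differs.

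**Figure D1:**
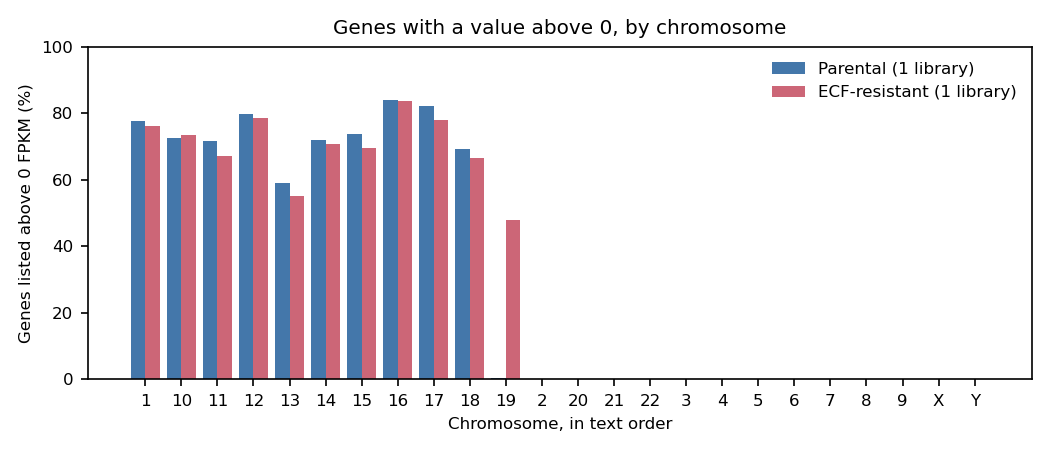
Percent of the genes of each chromosome listed above 0 FPKM in the parental library (blue) and the ECF-resistant library (red), with chromosomes in text order. Both libraries lie between 55.1% and 84.0% on chromosomes 1 and 10 to 18, the resistant library alone has a bar on chromosome 19, and the bars of the chromosomes after it lie at about 0.

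NINJ2, on chromosome 12, stood at 0.068 FPKM in the parental and 47.2 FPKM in the resistant library, a log2 ratio of 5.50 on the scale of FPKM plus 1. POSTN, which encodes the matrix protein periostin and lies on chromosome 13, was listed at 0 in both libraries. NINJ1 and VAV2 were also listed at 0 in both, but both lie on chromosome 9, where the tables hold no values. Of the 24 cancer-initiating cell markers listed, only 9 lie on chromosomes 1 and 10 to 18, so that most of the list could not be read. Among these, 7 genes reached 1 FPKM in at least 1 library, of which 3 were at least 2-fold higher and 2 at least 2-fold lower in the resistant library. CD44, a hyaluronan receptor, stood at 1.86 and 343 FPKM in parental and resistant cells. The aldehyde dehydrogenase gene ALDH1A3 was higher in the resistant library (12.5 against 51.8 FPKM) and the RNA-binding protein gene MSI1 was lower (12.6 against 2.36 FPKM). DCLK1 was also lower, at 1.27 FPKM in the parental library and listed at 0 in the resistant one. LGR5, a receptor of intestinal stem cells, stood at 0.010 and 1.53 FPKM. The median log2 ratio of this list was 0.54, at percentile 88.2 of 10000 random lists of the same size matched on expression, inside their central 95%.

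The genes with the highest log2 ratios on chromosomes 1 and 10 to 18 were PPP1R1B, ALDH3A1 and CRIP1, and those with the lowest were H19, SLC2A3 and OLR1. The protein phosphatase inhibitor gene PPP1R1B had the highest log2 ratio, with 1.42 FPKM in parental and 9904 FPKM in resistant cells. It was followed by the aldehyde dehydrogenase gene ALDH3A1 (0.056 against 1150.0 FPKM), CRIP1 (4.13 against 2985), the microsomal glutathione transferase gene MGST1 (1.10 against 948) and the actin-like gene ACTL8 (0.266 against 507). The gastrointestinal glutathione peroxidase gene GPX2 stood at 20.9 FPKM in the parental and 5878 FPKM in the resistant library. The matrix metalloproteinase gene MMP7 stood at 0.146 and 292 FPKM, the water channel gene AQP5 at 0.054 and 164 FPKM, and the mitochondrial carrier gene UCP2 at 1.22 and 271 FPKM. The aldo-keto reductase genes AKR1C2 and AKR1C3 stood at 211 and 1110.3 FPKM in resistant cells, against 0.463 and 7.98 FPKM in parental cells. The tetraspanin gene TSPAN8 was listed at 0 in the parental library and at 149 FPKM in the resistant one, and TSPAN1 stood at 0.650 and 214 FPKM. DNALI1, which encodes an axonemal dynein light chain, had 0.054 and 148 FPKM, and PDZK1IP1 0.587 and 194.01 FPKM.

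In the other direction, the imprinted noncoding RNA H19 stood at 11578 FPKM in the parental and 18.5 FPKM in the resistant library. The glucose transporter gene SLC2A3 stood at 639 and 0.264 FPKM, and its near-identical paralog SLC2A14, which may share its reads, at 102 and 0.107 FPKM. The oxidised lipoprotein receptor gene OLR1 had 497 FPKM in parental and 0.205 FPKM in resistant cells. SLC2A3, SLC2A14, OLR1 and TMEM52B all lie on chromosome 12, where stretches of neighbouring genes were lower together, as described below. The lowest genes therefore need not differ independently of each other. Genes of the cornified envelope were among the lowest, with SPRR3 at 339 and 0.439 FPKM and SPRR1B at 279 and 1.77 FPKM, as were S100A9 (233 against 1.42 FPKM), the protease inhibitor gene CST6 (217 against 0.130) and the epidermal transcription factor gene ZNF750 (99.7 against 0.165). SOX15 stood at 222 and 0.379 FPKM, and CHRNB1, which encodes a muscle acetylcholine receptor subunit, at 221 and 0.866 FPKM. TMEM52B (94.9 against 0.042 FPKM), QPRT (85.3 against 0.074) and the hair keratin gene KRT81 (78.7 against 0.117) completed this group with the neurotensin gene NTS, at 79.5 FPKM in the parental library and listed at 0 in the resistant one. The most abundant genes of the parental library were S100A11 (12609.7 FPKM), GAPDH (11899), H19, KRT18 (9365) and RPLP1 (8125). In the resistant library they were RPL19 (16742 FPKM), GAPDH (13508), PPP1R1B, ALDOA (9605) and RPLP2 (8718).

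**Figure D2:**
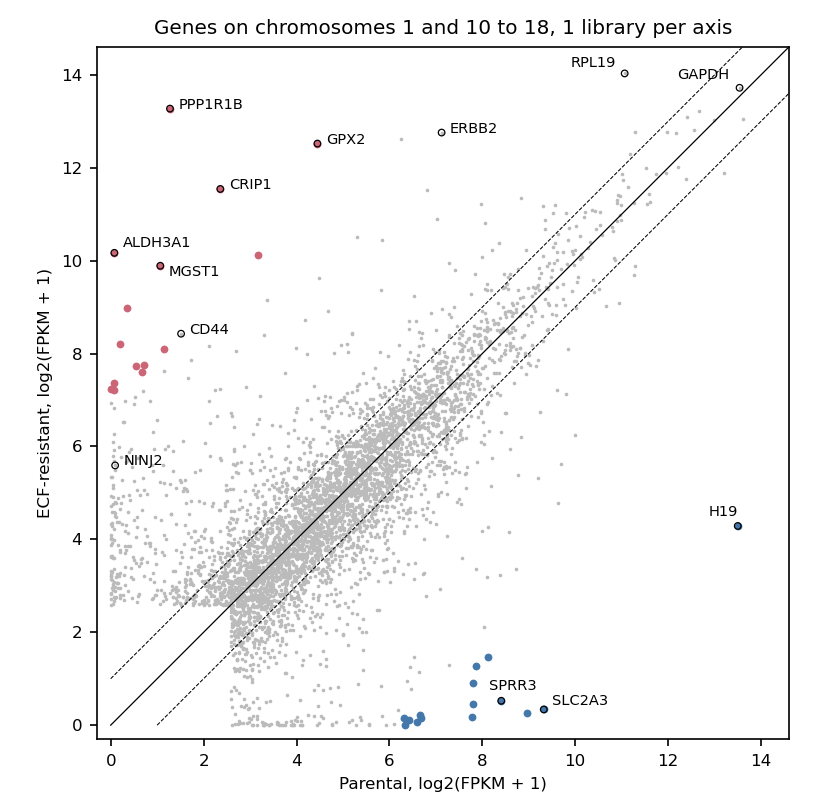
Log2 of FPKM plus 1 in the parental library (horizontal) against the ECF-resistant library (vertical), 1 point per gene on chromosomes 1 and 10 to 18 at 5 FPKM or more in at least 1 library. The solid line marks equal values, the dashed lines a 2-fold difference, red points the 15 highest and blue points the 15 lowest log2 ratios; PPP1R1B and H19 lie farthest from the solid line on either side.

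Of the 6066 genes on chromosomes 1 and 10 to 18 that reached 1 FPKM in at least 1 library, 973 were at least 2-fold higher and 889 at least 2-fold lower in the resistant library. After rescaling each library to the same sum these were 925 and 1341, so that which direction holds more genes depends on the scale. The correlation of log2 values across these genes, which are not independent replicates, was 0.791 (Pearson) and 0.787 (Spearman). The designed comparison over all 6682 genes gave 1515 higher and 904 lower, or 1400 and 1597 after the same rescaling, with correlations of 0.643 and 0.629. In it, 13 of the 15 highest log2 ratios belonged to chromosome 19 genes listed at 0 in the parental table, among them RPS16, FXYD5, RPS28, RPL36, CAPNS1, LSR, BSG, C19orf33, OAZ1, COX6B1, GPI and TECR. In resistant cells the genes named here stood between 787 FPKM for TECR and 4916 FPKM for RPS16. The 15 lowest genes did not depend on the restriction. The median log2 ratio of the 5189 genes on chromosomes 1 and 10 to 18 at 1 FPKM or more in both libraries was 0.0032, and it moved to -0.23 after rescaling each library to the same sum, so that ratios given here are relative to the values as deposited.

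Genes of drug and oxidant detoxification were higher in the resistant library as groups. All 15 measured NRF2 target genes, which the oxidant-sensing transcription factor NRF2 is known to drive, had log2 ratios above 0 and 10 were at least 2-fold higher, with a median of 2.01 at percentile 100. Apart from AKR1C2 and AKR1C3, the largest ratios were those of AKR1C1 (0.038 against 54.7 FPKM) and the transporter gene ABCC3 (8.81 against 336 FPKM). TRIM16L, at 97 and 97.4 FPKM, and SLC7A5 lay below 0 after rescaling to the same sum, while the list kept its place outside the central range. The list of anthracycline targets and reductases shares AKR1C1, AKR1C2, AKR1C3 and NQO1 with it, and 5 of its 7 measured genes were at least 2-fold higher (median 2.91, percentile 99.97). NQO1, a quinone reductase, stood at 253 and 1085 FPKM, and TOP2A, the topoisomerase that anthracyclines target, at 57 and 92.3 FPKM. The AKR1C genes are close paralogs whose reads can be assigned to the wrong member. Among the drug efflux transporters, 5 of 7 measured genes were at least 2-fold higher and none at least 2-fold lower (median 2.06, percentile 99.9). The largest ratios of this list, those of ABCC3 and ABCC2, belong to genes that the NRF2 list also holds. ABCC2 stood at 3.38 and 90.4 FPKM, the vault protein gene MVP at 9.58 and 61.2 FPKM, and ABCC1 at 29.3 and 125 FPKM. ABCB1 and ABCG2, on chromosomes without values, were not measured.

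The measured genes tied to the other components of ECF did not stand apart as groups. Only 17 of 28 platinum and thiol genes, 15 of 32 fluoropyrimidine genes and 15 of 37 repair genes lie on chromosomes 1 and 10 to 18. The others could not be read. In the list of platinum transport and thiol genes, 5 of 10 were at least 2-fold higher and 2 at least 2-fold lower (median 0.48, percentile 89.9), and the median lay below 0 with a filter at 5 FPKM. MGST1, GSTM3 (0.712 against 10.5 FPKM) and MGST3 (28.4 against 116 FPKM) were higher, and the metallothionein gene MT2A was lower (2471 against 821 FPKM). Among genes of fluoropyrimidine metabolism, 1 of 15 was at least 2-fold higher and 1 at least 2-fold lower (median 0.27, percentile 81.6). These were UCK2 (21.2 against 44.4 FPKM) and the dUTPase gene DUT (216 against 99.4 FPKM). Of the 15 measured genes of nucleotide excision and crosslink repair, only DDB2 passed 2-fold (18.5 against 39.7 FPKM). The median of the list was -0.03 (percentile 44.1), with a mean above 0, and the median lay above 0 with a filter at 5 FPKM.

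Gastric epithelial genes were higher in the resistant library and squamous genes lower. Of 13 gastric epithelial genes on chromosomes 1 and 10 to 18, 7 reached 1 FPKM in at least 1 library. Among these, 6 were at least 2-fold higher (median 4.64, percentile 100). After AQP5 and TSPAN8 they were led by the aspartic protease gene CTSE (0.794 against 125 FPKM) and the transcription factor gene GATA6 (0.611 against 39.1 FPKM). The remaining genes stayed under 1 FPKM in both libraries, among them MUC6 (0.033 against 0.025 FPKM) and LIPF (listed at 0 against 0.088 FPKM). The intestinal metaplasia list had 3 of 6 genes at least 2-fold higher (median 0.99, percentile 96.2), with the transcription factor gene CDX2 at 27.9 and 44.6 FPKM and the keratin gene KRT20 at 0.083 and 1.28 FPKM. Of 10 squamous keratinocyte markers, 8 were at least 2-fold lower (median -2.28, percentile 0). Beside the SPRR genes these included KRT6A (55.4 against 0.794 FPKM) and involucrin, IVL (5.87 against 0.026 FPKM), while KRT15 was higher (2.53 against 17 FPKM). Epithelial junction and keratin genes also had a median below 0 (-0.81, percentile 0), with 7 of 17 at least 2-fold lower and 2 higher. OVOL1 (94.4 against 18.4 FPKM), the tight junction gene TJP1 (195 against 41.5 FPKM) and CLDN7 (922 against 272 FPKM) had the largest differences. Over all genes this list's median stayed below 0 and its mean lay above 0, because 4 of its members are on chromosome 19 and listed at 0 in the parental table. The mesenchymal, p53 target and senescence lists also had a median below and a mean above 0 over all genes.

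Mesenchymal genes lay inside the central range, with 3 of 10 at least 2-fold lower and 1 higher (median -0.48, percentile 4.75). The calcium-binding protein gene S100A4 was higher in the resistant library (56 against 1392 FPKM), the collagen gene COL1A1 was lower (41.2 against 3.02 FPKM), and so was the membrane metalloproteinase gene MMP14 (67.1 against 9.49 FPKM). Among integrin and focal adhesion genes, 4 of 14 were at least 2-fold higher and 1 lower (median 0.27, percentile 80.8), including the laminin genes LAMA3 (0.066 against 22.7 FPKM) and LAMB3 (7.88 against 88.8 FPKM).

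YAP targets and interferon-stimulated genes were lower in the resistant library. All 13 measured genes of the YAP list had log2 ratios below 0, and 11 were at least 2-fold lower (median -2.11, percentile 0). Beside genes that the coactivator YAP1 is known to drive, the list holds YAP1 itself and the genes of its DNA-binding partners, TEAD1 and TEAD4. AMOTL1 stood at 46.5 and 0.022 FPKM, ANKRD1 at 19.9 and 0.141 FPKM, CYR61 at 186 and 26 FPKM and PTPN14 at 32 and 5.19 FPKM. Of 22 interferon-stimulated genes, 16 were at least 2-fold lower and 3 higher (median -1.74, percentile 0). The antiviral gene OAS2 stood at 92 and 1.78 FPKM and IFI6 at 791 and 26.4 FPKM, while LGALS3BP was higher in the resistant library (129.7 against 1906 FPKM), as was IFITM2 (14.9 against 276 FPKM), which has close paralogs. Inflammatory NF-kB genes were mixed, with 1 of 8 at least 2-fold higher and 3 lower (median -0.11, percentile 29.2). NFKBIA stood at 174 and 27.1 FPKM and TNFAIP2 at 9.95 and 54.2 FPKM. Only 4 genes of antigen presentation were measured, too few for a percentile (96.0 over all genes, with 5 measured), with NLRC5 at 1.76 and 7.45 FPKM and B2M at 359.7 and 692 FPKM.

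Wnt targets stood apart towards the resistant library, with 7 of 14 at least 2-fold higher and 4 at least 2-fold lower (median 0.85, percentile 99.8). Beside CD44, the Wnt antagonist gene DKK1 was listed at 0 in the parental library and at 19 FPKM in the resistant one, and BMP4 stood at 24.5 and 484 FPKM. APCDD1 had 37.7 FPKM in the parental library and was listed at 0 in the resistant one. Notch genes had 1 of 7 higher and 1 lower (median 0.70, percentile 93.6), with DTX1 at 0.298 and 3.68 FPKM and HES2 at 2.77 and 0.340 FPKM. None of 3 measured Hedgehog genes passed 2-fold, with SUFU at 20.4 and 15.1 FPKM and GLI1 at 1.38 and 2.06 FPKM. Of 8 receptor tyrosine kinases, 2 were higher and 1 lower. The median was 0.03, at percentile 48.2, and lay below 0 after rescaling to the same sum. ERBB2, the receptor also called HER2, stood at 138 FPKM in the parental and 6925 FPKM in the resistant library, and IGF1R at 48 and 12.7 FPKM.

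The unfolded protein response, amino acid response and immediate early lists had medians below the central range on chromosomes 1 and 10 to 18. None of these calls held in every setting and over both sets of genes. In the unfolded protein response, 5 of 11 genes were at least 2-fold lower and none higher (median -0.98, percentile 0.17), among them CHAC1 (436 against 40.5 FPKM) and ATF3 (57.7 against 8.90 FPKM), which the immediate early list also holds. Over all genes, the designed comparison, 5 of 12 were lower and 1 higher, and the median of -0.52 lay inside the central range at percentile 3.12. The member added there is CALR, on chromosome 19, listed at 0 in the parental table and at 559 FPKM in the resistant one. The place of this list thus depends on a gene whose parental 0 says nothing about its expression. The amino acid response list, which shares 3 measured genes with it, among them CHAC1 and SESN2 (105 against 22 FPKM), had 5 of 15 genes lower and 2 higher (median -0.50, percentile 1.59). Its percentile was 3.36, inside the central range, against random lists not matched on expression. Among immediate early genes, 5 of 10 were lower and 3 higher (median -1.08, percentile 0.11). NR4A1 stood at 78.8 and 17.2 FPKM, and the phosphatase gene DUSP6 was higher (3.05 against 17.2 FPKM). Over all genes this median turned to 0.92, at percentile 99.4, because 4 members on chromosome 19 are listed at 0 in the parental table. Of 14 p53 targets, 3 were higher and 5 lower (median -0.40, percentile 7.75), with MDM2 at 77.9 and 23.8 FPKM and BTG2 at 8.58 and 29.5 FPKM. Heat shock genes had 4 of 10 higher (median 0.61, percentile 97.0), led by HSPA8 (656 against 1876 FPKM) and AHSA1 (48.8 against 129 FPKM). In the BCL2 and apoptosis inhibitor families, 2 of 13 genes were lower, BCL2L2 (7.21 against 1.77 FPKM) and BIRC2 (25.9 against 11.4 FPKM). The median of 0.10 (percentile 60.1) and the mean of -0.15 had opposite signs, and the median lay below 0 after rescaling to the same sum. Of 6 senescence-associated secretory genes on chromosomes 1 and 10 to 18, only 3 reached 1 FPKM in at least 1 library. They were led by SERPINB2, at 4.55 FPKM in the parental library and listed at 0 in the resistant one, and CCL2 (3.18 against 0.095 FPKM).

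Mitotic genes had a median of -0.51 (percentile 0.61), with 15 of 18 log2 ratios below 0 and 3 above. Most of these differences were under 2-fold, and only KIF23 (85.5 against 24.4 FPKM) and AURKB (239.9 against 98 FPKM) passed it. DNA replication genes of S phase had a median of 0.41 (percentile 94.7), and only CDC6 of 15 passed 2-fold (34.3 against 114 FPKM), while POLE stood at 39.8 and 22.6 FPKM. Of 5 measured histone genes, HIST2H3D was higher (0.374 against 2.15 FPKM) and HIST2H2AC lower (2.24 against 0.469 FPKM), at a list median of 0.01 and percentile 45.6, and the median lay below 0 after rescaling to the same sum. Nuclear genes of oxidative phosphorylation stood apart, with 4 of 21 at least 2-fold higher and none lower (median 0.60, percentile 99.7), led by ATP5G1 (295 against 1199 FPKM) and NDUFB10 (166 against 509.6 FPKM). Hypoxia and glycolysis genes had 5 of 23 higher and 4 lower (median 0.32, percentile 89.6). Beside SLC2A3, EGLN3 (1.25 against 60.9 FPKM) and ALDOC (8.26 against 135 FPKM) differed most. Cholesterol synthesis had 4 of 11 genes higher (median 0.62, percentile 97.1), with MVD at 11.7 and 42.1 FPKM. Fatty acid and lipid synthesis had 3 of 12 higher and 3 lower (median -0.05, percentile 33.5), with the desaturase gene FADS1 at 11 and 0.023 FPKM and ACSL5 at 8.18 and 95.2 FPKM. Ribosomal protein genes had 7 of 30 higher (median 0.43, percentile 96.1), with RPL21 at 0.013 and 14.2 FPKM, RPL19 at 2141 and 16742 FPKM and RPL23 at 91.6 and 607 FPKM. Over all genes, 13 of 36 were higher and the median of 0.49 lay outside the central range at percentile 99.5, but inside it at 97.34 against random lists not matched on expression, and 6 of these genes are on chromosome 19 and listed at 0 in the parental table. Many ribosomal protein genes have pseudogenes that can share reads. None of 10 housekeeping genes passed 2-fold (median 0.27, percentile 72.3), with GAPDH at 11899 and 13508 FPKM and RPLP0 at 2037 and 2331 FPKM.

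**Figure D3:**
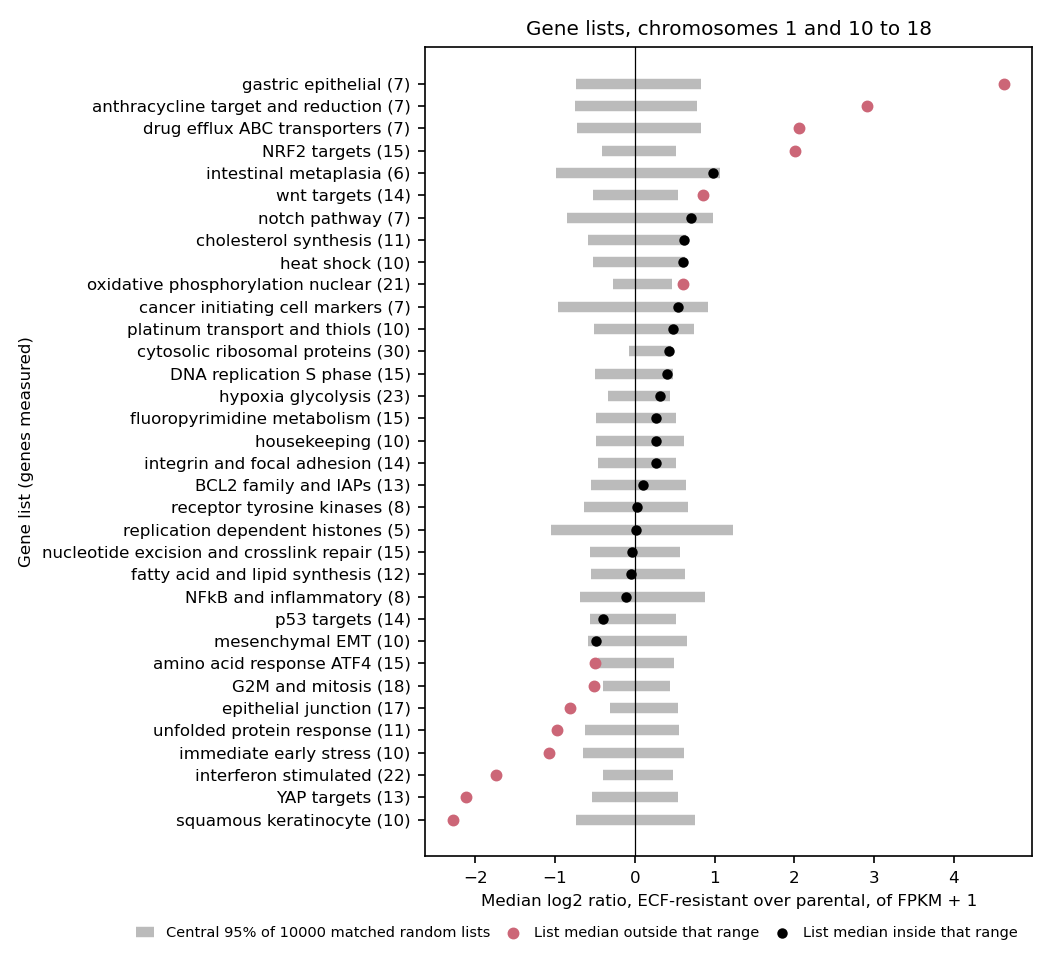
Median log2 ratio (ECF-resistant over parental, of FPKM plus 1) of each gene list on chromosomes 1 and 10 to 18 with at least 5 measured genes. Grey bars show the central 95% of 10000 random lists matched on expression, and red points mark the 14 of 34 medians outside that range, from squamous keratinocyte markers at -2.28 to gastric epithelial genes at 4.64.

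Of the 34 lists with a percentile, 6 lay above and 8 below the central 95%, where 1.7 would lie outside for lists of genes drawn at random. Genes of a list can vary together, unlike genes drawn at random, and some lists share members. The number outside therefore does not measure an excess over chance. Over all genes, 36 lists had a percentile, with 8 above and 6 below. The calls of the immediate early, unfolded protein response and ribosomal protein lists differed between both sets of genes. Markers of other cell types could be read only in part, because many lie on chromosomes without values. Of 6 fibroblast markers on chromosomes 1 and 10 to 18, only COL1A1 and ACTA2 (3.23 against 2.92 FPKM) reached 1 FPKM, and of 6 endothelial markers there only ESAM did (56.8 against 20.5 FPKM). Leukocyte markers went both ways, with CORO1A at 42.2 and 3.86 FPKM, CD68 at 17.6 and 127 FPKM, LCP1 at 4.03 and 0.770 FPKM and LYZ at 13 and 22.1 FPKM. The globin gene HBA1 stood at 1.61 and 8.91 FPKM. Of the neuroendocrine and neuronal markers, ENO2 stood at 2.11 and 31.8 FPKM, GAST at 10.8 and 8.56 FPKM and TUBB3 at 93 and 101 FPKM. Of the 30 cancer-testis antigens listed only 2 lie on these chromosomes, and neither reached 1 FPKM, so that the others were not measured. None of the 15 mitochondrially encoded genes listed was found in the deposited tables, so that this list could not be read.

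Genes next to ERBB2 on chromosome 17 were higher in the resistant library together, a comparison made after their values were seen. MIEN1 stood at 74.7 and 6265 FPKM, the adaptor gene GRB7 at 112 and 2917 FPKM, STARD3 at 38.5 and 1463 FPKM and PGAP3 at 9.33 and 571 FPKM, with PPP1R1B among the same neighbours. Over genes at 5 FPKM or more in at least 1 library, the highest median over 15 neighbouring genes was 2.97, around ERBB2, and none of 1000 random gene orders reached it, the highest being 2.35. The lowest such median, -3.66, lay on chromosome 1 in the epidermal cluster around SPRR3 and S100A9, against a lowest value of -2.02 in random orders. With 25 neighbouring genes the highest median was 2.64, again on chromosome 17 and above all random orders. The lowest was -1.15, which 1 of the 1000 random orders reached, and it lay on chromosome 17, while the epidermal cluster no longer stood out.

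**Figure D4:**
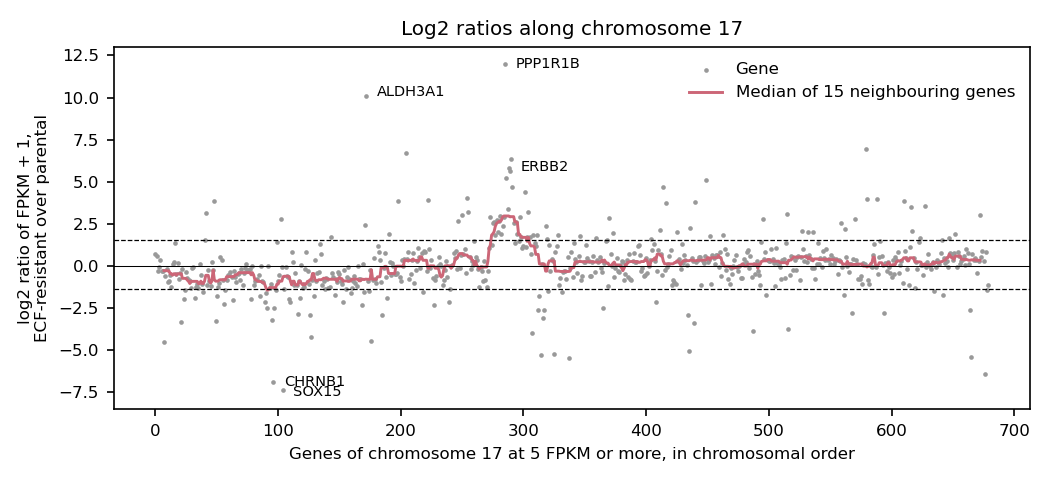
Log2 ratio (ECF-resistant over parental, of FPKM plus 1) of each gene of chromosome 17 at 5 FPKM or more in at least 1 library, in chromosomal order (grey points), with the median over 15 neighbouring genes (red line). Dashed lines at 1.56 and -1.34 bound the highest and lowest medians in 95% of random gene orders each, and the red line passes the upper one around ERBB2, where it reaches 2.97, and again just beside it at 1.70, and the lower one in a stretch that reaches -1.43.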

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

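Both tests in this part were chosen after the result was seen. On chromosome 19 the resistant library had 741 genes above 0, outside the comparison on chromosomes 1 and 10 to 18, while the parental library had 3. They were picked out as a signal in data that the leading comparison does not use. A lack of expression of the genes listed at 0 is argued against by the ribosomal protein genes: 0 of 33 were above 0 on the chromosomes after 19, and 30 of 30 were above 0 in both libraries on chromosomes 1 and 10 to 18. A candidate explanation is that the tables stop partway through the chromosomes in text order, at different places in the 2 libraries. Up to CEACAM6, 81.0% of the chromosome 19 genes of the resistant library were above 0, inside the range of its other chromosomes. That 0 of the 627 genes after it were above 0 follows from taking CEACAM6 as the last gene with a value. Only the length of that run carries information. Why the tables stop there was not tested.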

How the results depend on the processing

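No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. Depth is unknown, so what it limits could not be computed. Over all genes, a pseudocount of 5 gave 1008 genes at least 2-fold higher and 522 lower, rescaling to the same sum 1597 lower, a 1.5-fold threshold 1541 lower, and a 4-fold threshold 846 higher and 277 lower. Restricting to chromosomes 1 and 10 to 18, an alternative added after seeing the data like each of its variants, gave 973 higher, with correlations of 0.791 (Pearson) and 0.787 (Spearman). Over all genes the Pearson correlation was 0.503 with a pseudocount of 0.1 and 0.873 with no filter, and the Spearman correlation 0.867 with no filter, where 24391 genes enter. Within the restriction, a pseudocount of 5 gave 589 higher and 517 lower, rescaling to the same sum 1341 lower, 1.5-fold 1584 and 1518, and 4-fold 383 and 274. The Pearson correlation was 0.711 with a pseudocount of 0.1, and with no filter both were 0.906. Of genes past 2-fold over all genes, 62.6% were higher, against 46.7% after rescaling to the same sum and 50.2% after upper-quartile scaling, and within the restriction 52.3% against 40.8%. Rescaling to the same sum moved the median of all genes to -0.39, and upper-quartile scaling to -0.31. With no filter, the lists above the central range numbered 5 over all genes, against 8, and 10 within the restriction, against 6. The median of immediate early genes turned from 0.92 to -1.08 under the restriction, which drops the chromosome 19 genes listed at 0 in the parental table. Among the other list medians over all genes, 293 values under an alternative kept their side of the central range, 20 of them with a median that turned its sign, 17 moved out of the central range and 9 into it, 7 of these at a median of 0 with no filter. Within the restriction the numbers were 253, 7, 15 and 1. The 7 lists at a median of 0 with no filter over all genes were those of epithelial junction, interferon-stimulated, amino acid response, Wnt target, gastric epithelial, ribosomal protein and immediate early genes. The genes of the study's question and the 15 highest and 15 lowest kept their side of 2-fold in all 170 and 160 values, and other genes were not recomputed here. That outcome was largely fixed in advance. NINJ1, POSTN and VAV2, listed at 0 in both libraries, have a log2 ratio of 0 under each of these settings. The 15 highest and 15 lowest were chosen for their extreme ratios. Using the first entry per symbol could change no count, because gene symbols were unique. Beyond the fewer or more genes entering, the cause of these shifts was not tested.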

Other observations

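Some genes of motile cilia, which normally mark multiciliated cells, were higher in the resistant library. The list of 49 genes, all on chromosomes 1 and 10 to 18, was written after DNALI1 and others had been seen, so its position is not independent evidence. Of the 22 members that reached 1 FPKM in at least 1 library, 12 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.33 at percentile 100, and 27 members stayed under 1 FPKM in both libraries. FOXJ1, the transcription factor that drives motile cilium formation, was listed at 0 in the parental library and at 121 FPKM in the resistant one. CFAP126 stood at 0.627 and 146 FPKM, TPPP3 at 0.052 and 50.2 FPKM and PIFO at 0.920 and 60.7 FPKM.

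Some genes were abundant in 1 library and nearly absent from the other. On chromosomes 1 and 10 to 18, 32 of the 1377 genes at 50 FPKM or more in the resistant library were under 1 FPKM in the parental one, and 20 of 1353 the other way round. By chromosome, the median log2 ratio of genes at 5 FPKM or more in at least 1 library was highest on chromosome 18 (0.59 over 115 genes) and lowest on chromosome 15 (-0.47 over 340 genes).

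The tests of the following patterns were chosen after the results were seen. Neighbouring genes differed in stretches, 2 higher and 5 lower in the resistant library with windows of 15 genes, and 7 higher and 6 lower with windows of 25 genes, after overlapping ones of the same direction were merged. Their number depends on the window, and with 25 genes 2 of the higher ones overlapped 2 of the lower ones. With 15 genes, the lower ones included 16 genes from APOBEC1 to YBX3 on chromosome 12, 8 at least 2-fold lower and 1 higher. Another on chromosome 12 held 16 genes from LETMD1 to KRT8, 9 at least 2-fold lower and 0 higher. On chromosome 14, 16 of 29 genes from SDR39U1 to PNN were at least 2-fold higher and 3 lower, among them the signal recognition particle gene SRP54 (17.8 against 253 FPKM) and the transcription factor gene FOXA1 (1.84 against 36.7 FPKM). A chance order of genes is argued against by the random orders, whose highest median was 2.35 against 2.97 around ERBB2. The median log2 ratio over genes on chromosomes 1 and 10 to 18 at 1 FPKM or more in both libraries was 0.0032, or -0.23 after rescaling to the same sum. A difference in scale would move all genes about alike, so that this median is no test of stretches that go both ways. A candidate explanation for the ERBB2 stretch is a gain of gene copies in the resistant cells, either selected under ECF or carried by a different starting population, and the epidermal cluster on chromosome 1 may instead follow shared regulation. These were not tested, because the values hold no copy number and no genotype, and whether both libraries come from 1 line was not tested either.

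The fibroblast marker COL1A1 was higher in the parental library, at 41.2 against 3.02 FPKM. Fibroblasts mixed into the parental library are argued against by DCN, LUM, THY1 and POSTN, on the chromosomes with values, which were all listed at 0 in that library, so that their highest value was 0. ACTA2, the other fibroblast marker on these chromosomes, was left out of that test because epithelial cultures also show it, and it stood at 3.23 FPKM in the parental and 2.92 FPKM in the resistant library. The cause of the difference stays open.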
